A study of Mus musculus with 9 samples.

How the data were processed

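Single-cell RNA sequencing was analysed from 9 libraries of mouse ETiX structures, models of the embryo around implantation that are built from cultured stem cells. Embryonic stem cells (ESCs) form the epiblast (EPI), ESCs with an inducible Gata4 gene (iGata4) form the visceral endoderm (VE), and trophoblast stem cells (TSCs) form the extraembryonic ectoderm (ExE). In each of 3 series, 1 of these cell types had been pre-treated with reversine, an inhibitor of the spindle checkpoint kinase Mps1 that causes chromosome missegregation, or with its solvent DMSO. Each series has the groups DD (DMSO cells), DA (DMSO and reversine cells mixed 1:1) and AA (reversine cells), with 1 library per group. Per the design text, differently labelled cells were mixed in DD and AA too, and about 200 structures of day 3 were used. The groups were taken from the sample titles.

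The deposited values are raw UMI counts per gene and barcode. Per the file headers they were made with Cell Ranger 6.1.2, and per the submitters' processing notes the genome build was mm10. All 9 files state the same version. The lowest UMI count of a barcode was 500 or 501 in each library. Total UMIs ranged from 60019384 in TSC DD to 131451843 in iGata4 AA, and barcodes from 10966 to 16405. Gene positions came from GENCODE M21, in which 32235 of 32285 genes were found. Reads of near-identical copies, such as ribosomal protein pseudogenes, cannot be assigned with certainty, and their values are uncertain. Xist and genes of the Y chromosome were left out of the genes named.

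Barcodes with at least 500 genes and at most 25% mitochondrial UMIs were clustered together (scanpy 1.11.5, 2000 variable genes, 30 principal components, 15 neighbours, leidenalg 0.10.2; Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0). Clusters were named EPI-like, VE-like or ExE-like from fixed markers. Clusters 6 and 7 were named parietal-endoderm-like and kept apart, clusters 8, 12, 17 and 21 were mostly cells called doublets (51.6% to 87.8%), clusters 11, 18 and 19 had few UMIs, and cluster 20 had genes of the 2-cell-like state. The analysed cells had at least 1000 genes, at most 15% mitochondrial UMIs and a named cluster, and were not called doublets by Scrublet (run through scanpy per library; 3.16% to 12.0% of cells called). They numbered from 8638 in ESC AA to 11644 in iGata4 AA, with the parietal-endoderm-like and unnamed cells counted, and their median UMIs ranged from 3621 in TSC DD to 9322.5 in ESC AA.

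Cells are not replicates, so counts were summed per library and class, and libraries were the units. Sums were compared with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood F test; R 4.3.3) and Benjamini-Hochberg adjusted p under 0.05. The shared response used the treated lineage of each of the 9 libraries with lineage as a block (4 residual degrees of freedom). The response of each lineage used its sums in all 9 libraries with series as a block, in which the spread comes from the series where another lineage was treated (4 degrees). These p-values assume that the lone DD, DA and AA libraries vary like those of the other series. Changes between DD, DA and AA in those series count as spread in this fit and raise the error. Few calls in a treated lineage therefore do not show a small response, or one smaller than in untreated cells. The difference between lineages was a test of both interaction coefficients (3 degrees), and the response of untreated cells used the 6 libraries of the other series (2 degrees). Gene lists and chromosomes were tested with limma camera 3.58.1 on log-CPM (prior count 2, inter-gene correlation 0.01) and again with an estimated correlation, with adjustment over 30 or 31 lists or 20 chromosomes within each fit. A list needed 5 measured members, and 32 lists were drawn up.

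Shares of cells were compared as the AA minus DD difference in log-odds, averaged over the 3 series, with an exact two-sided permutation test over the 216 ways to permute the labels within series, whose smallest p is 0.009. Intervals of shares are exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only. For the dispersion of chromosome shares, cells with at least 5000 autosomal UMIs were thinned to 5000, and cells with fewer were left out. The variance between cells of the share of each of 19 autosomes, less its binomial part, was expressed as a coefficient of variation in percent and averaged. The same permutation test was used.

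The named genes have no clone or predicted-gene name. They are up to 10 rises and 10 falls with the largest change among those that passed, with at least 20 CPM and the same sign in the 3 lineages (shared response) or in DA (lineage responses). Where fewer than 3 passed, they are the 5 with the smallest p in that direction. Up to 4 members of each list that passed and 12 p53 targets complete the rule, and the text names a part of the list members. Some genes that the rule takes are not reported here. For the response of untreated cells, the same sign was required in both series. Tests, groups, markers, lists, cell filters, alternatives and this rule were set before the data were examined, except where the text says otherwise. The alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, doublets kept, a strict filter (2000 genes, 10% mitochondrial), cells thinned to 5000 UMIs, a linear effect of the reversine share, and each library left out. Cells under 5000 UMIs were left out of the thinned sums.

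The tests were tested on simulated data with 200 genes changed. In the shared response, 7.69% of genes changed 1.5-fold, 45.5% of those changed 2-fold and 82.8% of those changed 4-fold were recovered, with 11 unchanged genes among 99 calls. In the EPI-like and ExE-like responses, 0% were recovered at any fold, and in the VE-like response 0%, 1.52% and 32.8%. For untreated cells, recovery at 2-fold was 56.7% in EPI-like, 61.5% in VE-like and 70.1% in ExE-like cells, with 28 unchanged genes among 136 calls, 3 among 110 and 15 among 135, so false calls can exceed the nominal 5%. For the difference between lineages it was 13.6% at 4-fold. A list with members raised 1.5-fold was called in each of the 7 fits tried, with 0 other lists called. Genes were simulated independently of each other, so this does not test false calls of lists whose members vary together. With 10% of simulated cells carrying 1 chromosome gain or loss the excess coefficient of variation was 2.87 against a true value of 3.63, and with 0% it was -0.362. The simulated cells did not differ otherwise, whereas treated lineages of DMSO libraries stood at 6.59 (ESC DD), 7.53 (iGata4 DD) and 7.24 (TSC DD). The simulation thus does not show detection above that level, and measured values do not give a share of altered cells.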

Results

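Gene expression was measured in single cells of ETiX structures, stem-cell models of the mouse embryo around implantation that hold EPI, VE and ExE compartments. In the ESC series the EPI precursors had been pre-treated with reversine, a drug that makes cells missegregate chromosomes. In the iGata4 series it was the VE precursors, and in the TSC series the ExE precursors. Each series has 3 libraries: DD from DMSO-treated cells, DA from a 1:1 mix of DMSO-treated and reversine-treated cells, and AA from reversine-treated cells. Each group is 1 library, so no group has replicates of its own. Depth ranged from 60019384 UMIs in TSC DD to 131451843 in iGata4 AA. In each series the AA library had the highest median UMI count per analysed cell, 9322.5 in ESC AA, 8977 in iGata4 AA and 8271 in TSC AA, against 3621 to 6536 in DD and DA.

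Cells expressing EPI markers such as Pou5f1 and Utf1, VE markers such as Amn and Ttr, and ExE markers such as Elf5 and Rhox6 were found in all 9 libraries. Most classes lay in other clusters in AA than in DD, except VE-like and ExE-like cells of the TSC series. EPI-like cells of ESC DD lay in cluster 13 (91.4%), and those of TSC DD in cluster 14 (93.5%), whereas 86.1% to 97.6% of EPI-like cells of the AA libraries lay in cluster 15. VE-like cells of ESC DD lay in cluster 4 (94.2%), those of iGata4 DD in clusters 10 (57.1%) and 4 (40.1%), and those of TSC DD mostly in cluster 5 (71.5%), as did those of the AA libraries (94.7% to 99.4%). ExE-like cells of the ESC and iGata4 series lay mostly in clusters 0 and 1 in DD and DA, and in clusters 2 and 9 in AA. Those of the TSC series lay in cluster 3 in DD (89.5%), DA (90.5%) and AA (82.4%). A cluster held mostly by AA libraries may be those libraries rather than a cell state.

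The first comparison asked whether the lineage made from treated cells takes a smaller share of the cells. EPI-like cells of the ESC series were 15.5% of the cells of the 3 lineages in DD (95% interval 14.8% to 16.3%), 13.7% in DA (13.0% to 14.5%) and 11.6% in AA (10.8% to 12.3%). VE-like cells of the iGata4 series were 28.9% in DD (27.9% to 29.8%), 22.5% in DA (21.7% to 23.4%) and 3.21% in AA (2.87% to 3.59%). ExE-like cells of the TSC series were 14.1% in DD (13.3% to 14.8%), 10.9% in DA (10.2% to 11.5%) and 31.2% in AA (30.3% to 32.2%). The AA minus DD difference in log-odds averaged -0.608 over the series (ESC -0.343, iGata4 -2.50, TSC 1.02) and did not pass an exact permutation test (p = 0.444, smallest possible 0.009). With parietal-endoderm-like cells counted as VE-like, the iGata4 values were 32.5%, 23.9% and 14.9%, the iGata4 difference -1.01 and the average -0.103. Without the iGata4 series the average was 0.338, and without the TSC series -1.42. With the strict cell filter ExE-like cells were 25.3% in TSC DD, 12.7% in DA and 31.9% in AA, and the TSC difference was 0.324 and the ESC difference -0.134. Untreated lineages moved as well: EPI-like cells fell from 25.6% to 6.94% between iGata4 DD and AA and from 58.8% to 33.4% between TSC DD and AA, without a test. The TSC values were 33.7% and 30.7% with the strict filter. Assembly, dissociation and capture can set these shares. The shares of a library are parts of 1 whole, so a change in 1 lineage moves the others.

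**Figure D1:**
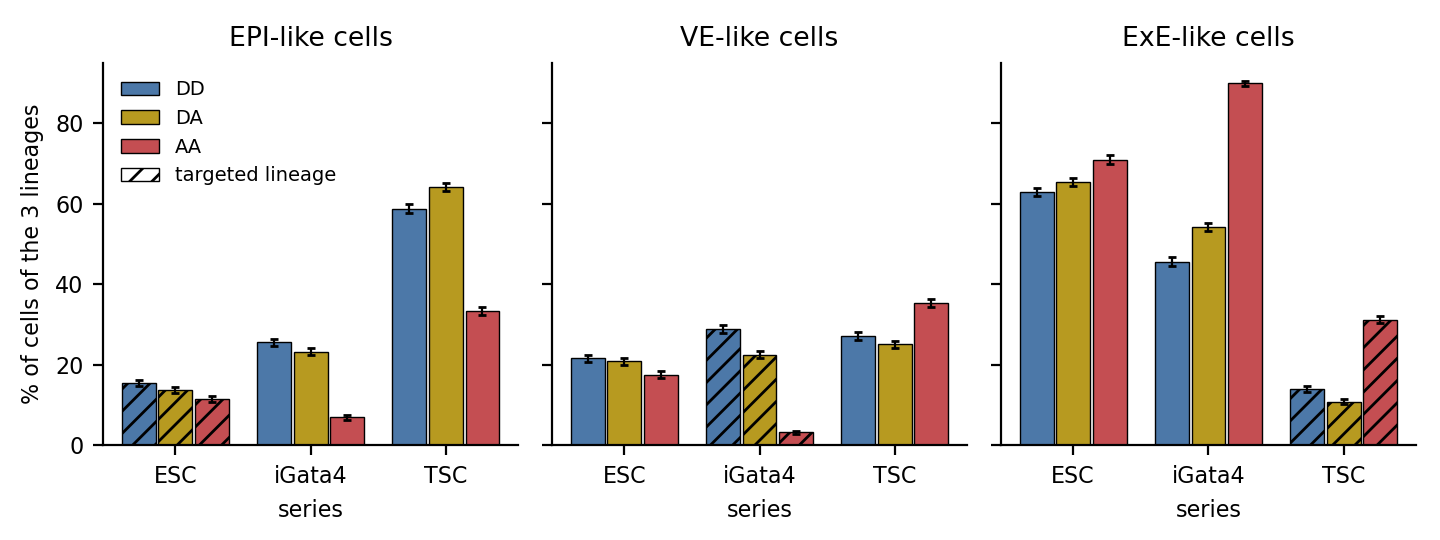
Percent of cells of the 3 lineages that were EPI-like, VE-like or ExE-like in each of the 9 libraries, with bars for exact 95% binomial intervals and hatching for the lineage made from treated cells; parietal-endoderm-like cells are not counted. VE-like cells of the iGata4 series fell from 28.9% to 3.21% between DD and AA, and ExE-like cells of the TSC series went from 14.1% to 31.2%.

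The inducible heat-shock genes Hspa1a and Hspa1b, whose products refold damaged proteins, rose in AA against DD over the 3 treated lineages, by 4.93 (SE 0.82, adjusted p = 0.0244, edgeR) and 3.92 on the log2 scale. Hspa1a went from 1.37 to 163 CPM in EPI-like cells of the ESC series. In ExE-like cells of the TSC series it went from 6.92 to 196 CPM, but in VE-like cells of the iGata4 series only from 0.718 to 1.11 CPM. Untreated VE-like and ExE-like cells of ESC AA had 69.2 and 188 CPM. Untreated EPI-like and VE-like cells of TSC AA had 124 and 38.4 CPM. Untreated EPI-like and ExE-like cells of iGata4 AA had 5.59 and 7.31 CPM. The small rise in VE-like cells thus goes with the iGata4 AA library and is not shown to be specific to that lineage. Ddit3, which encodes the stress transcription factor CHOP, rose by 1.99 (adjusted p = 0.0132), and Maff, a small Maf factor of the oxidative stress response, by 1.79. Gstp1, a glutathione transferase, rose by 2.42, Rpa3, a subunit of the single-strand DNA binding complex, by 2.04, and the host gene Snhg6 by 1.86. BC004004 rose by 2.67 (SE 0.22, adjusted p = 0.000339), from 16.7 to 169 CPM in EPI-like, from 21.1 to 88.8 CPM in VE-like and from 17.1 to 110 CPM in ExE-like cells. The retrocopy Rpl39l (2.89) rose too, and shares reads with its parent gene.

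The largest fall was that of Bc1, a small brain cytoplasmic RNA (chromosome 7, 144914470 to 144914637, mm10). It went from 44.6 CPM to 0 counts in EPI-like cells (0 counts allow up to 0.404 CPM), from 111 CPM to 0 counts in VE-like cells (up to 0.833 CPM) and from 138 to 0.267 CPM in ExE-like cells. Its fitted log2 change of -9.09 (adjusted p = 4.29e-06, edgeR) depends on the prior count. Rnaset2a, a ribonuclease, fell by 3.70, Xaf1, an interferon-induced promoter of apoptosis, by 3.50, Cdk2ap1, a CDK2-associated protein, by 2.30, Dennd5b, a Rab exchange factor, by 2.05 and Hypk, a huntingtin-interacting chaperone, by 1.90. Nutf2-ps1 (-4.44), Rpl9-ps6 (-2.54), Rpl10-ps3 (-2.17) and Rps27rt (-2.15) fell too, and their levels are uncertain because their reads match parent genes. In all, 313 of 13358 genes passed, 149 higher and 164 lower in AA, and DESeq2 called 733. The count rested on single libraries: it was 43 without TSC DD, 51 without iGata4 DD, 67 without ESC DD, 153 without iGata4 DA, 189 without ESC DA, 201 without iGata4 AA and 1623 without TSC AA. BC004004, Bc1, Nutf2-ps1, Rnaset2a, Xaf1, Rpl9-ps6, Cdk2ap1, Rpl10-ps3, Rps27rt, Dennd5b, Hypk, Plac1, Fgf5 and Snrpn passed with each library left out, and the other genes named as passing in this response lost their call without at least 1 library, most often a DD library.

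The changes were not confined to treated cells. Of the 313 genes, 310 (99.0%) had the same sign in the untreated lineages of the same libraries. The median change there, signed in the direction of the treated lineages, was 0.87 as a mean of log2 CPM differences. The median absolute change fitted by edgeR in the treated lineages was 1.20. These measures differ, and the genes were selected in the treated lineages, so the sizes are not directly comparable. Among the 13045 genes that did not pass, 76.3% had the same sign. When the untreated lineages of each library were subtracted, limma called 0 genes, with 727 at an unadjusted p under 0.05. Hspa1a then stood at -0.98, BC004004 at -0.25 and Rnaset2a at 0.21, none of which passed. Recovery was not simulated for this subtraction, so 0 calls do not show that no change was larger in treated lineages. In each class of each AA library, Bc1, Rpl10-ps3, Rnaset2a, Rpl9-ps6 and Nutf2-ps1 were lower and BC004004 higher by over 2-fold than in the DD and DA libraries.

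**Figure D2:**
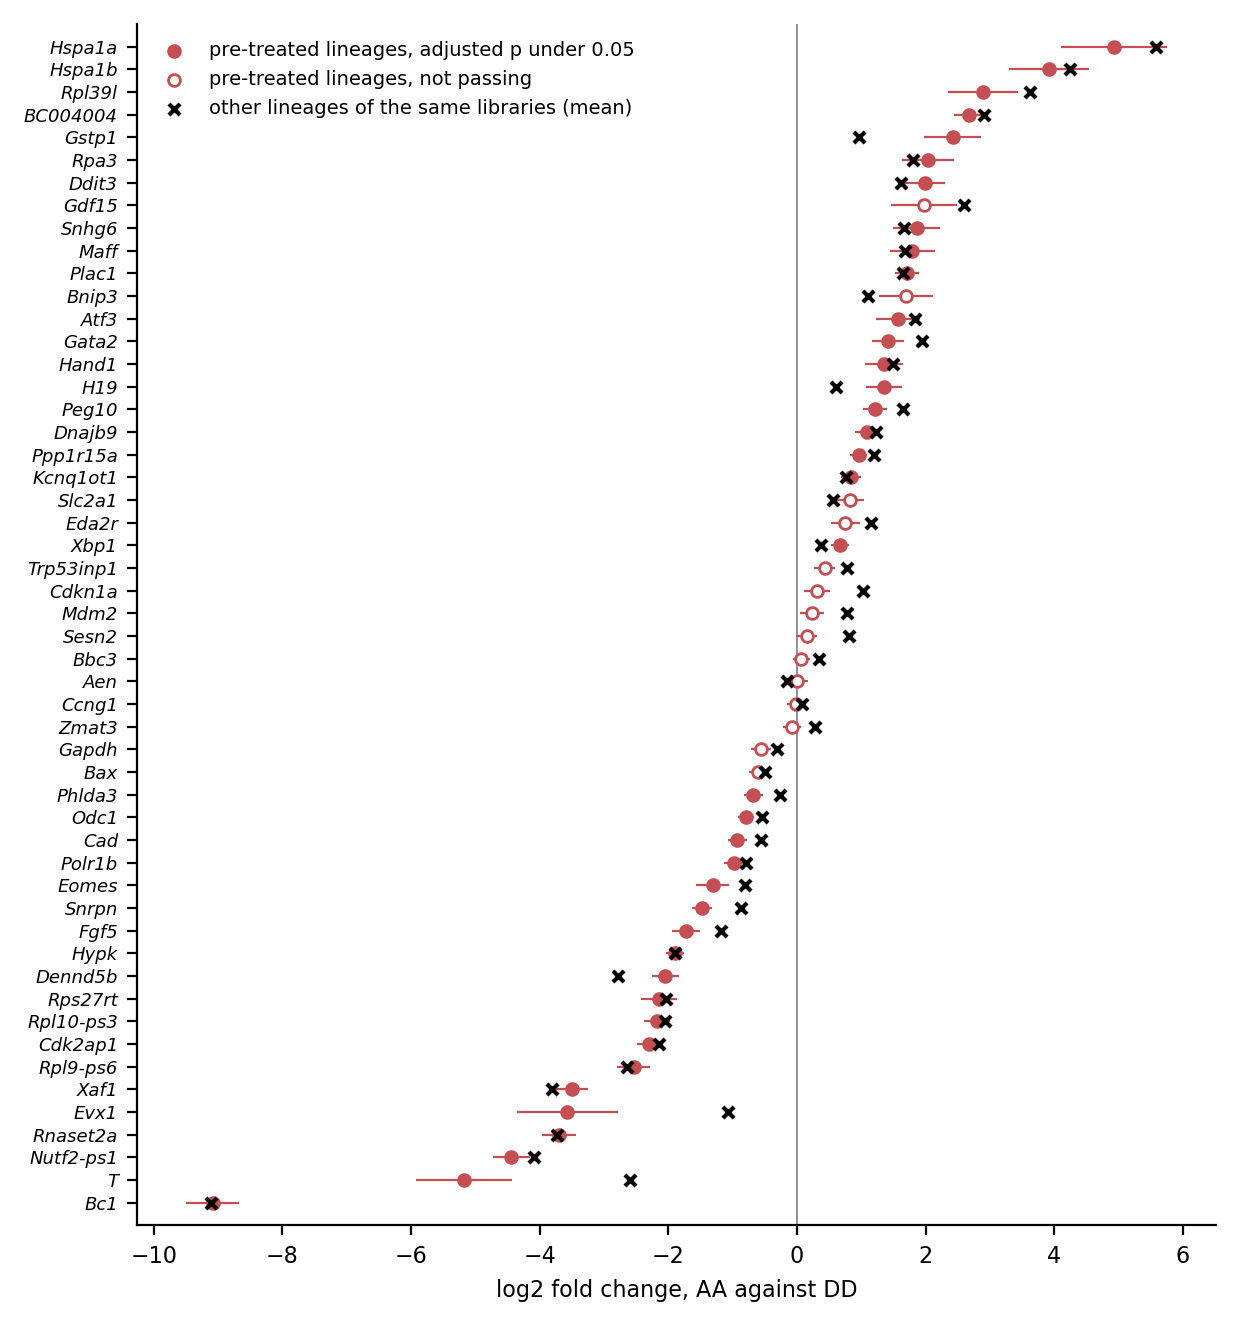
Log2 change of named genes between AA and DD in the treated lineages with standard errors (filled, adjusted p under 0.05 in edgeR; open, not passing), and crosses for the mean of the untreated lineages of the same libraries. Bc1 fell and Hspa1a rose in treated and untreated lineages.

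Of 12 measured genes of trophoblast differentiation, 12 were higher in AA in the treated lineages (median 1.03, camera adjusted p = 0.000167, or 0.389 with an estimated correlation), and 4 passed. These were Plac1 (1.71, adjusted p = 0.00139, edgeR), Peg10 (1.21) and Gata2 (1.41), which act in the placenta, and Hand1 (1.35), a regulator of giant cells. RNA of ExE-like cells was not removed from the other classes, and their share went from 45.6% to 89.9% between iGata4 DD and AA, so background can add to these values. The unfolded protein response had 17 of 22 members higher (median 0.30), of which 4 passed: Ppp1r15a (0.96) and Atf3 (1.57) of the integrated stress response, Xbp1 (0.67) and its target Dnajb9 (1.08). Imprinted genes had 17 of 23 members higher (median 0.55). H19 (1.35) and Kcnq1ot1 (0.84) were among 3 that rose, and Snrpn fell by 1.48 (adjusted p = 0.00129). Glycolysis and hypoxia genes had 18 of 22 members higher (median 0.62), but 0 passed over all genes. The glucose transporter Slc2a1 stood at 0.82 (adjusted p = 0.0754, edgeR), Bnip3 at 1.69 and Gapdh at -0.56. Adjusted over the list alone, 8 trophoblast, 8 unfolded protein response, 10 imprinted and 7 glycolysis genes rose.

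Of 23 genes of ribosome biogenesis, 21 were lower (median -0.32, camera adjusted p = 0.000961, or 0.389 with an estimated correlation). Odc1, which starts polyamine synthesis, fell by 0.80 (adjusted p = 0.0118, edgeR), Cad of pyrimidine synthesis by 0.93, and Polr1b of RNA polymerase I by 0.99, and the other 20 did not pass. All 18 cholesterol synthesis genes were lower (median -0.49). Primitive streak genes had 7 of 8 measured members lower (median -2.66). T, the streak regulator brachyury (-5.18), Evx1 (-3.57) and Eomes (-1.31) passed, T and Evx1 resting on EPI-like cells, where T went from 48.5 to 0.809 CPM. In VE-like and ExE-like cells T was under 0.2 CPM in DD. Of 16 formative pluripotency genes, 11 were lower (median -0.11), and Fgf5 (-1.72) passed. Adjusted over the list alone, 6 ribosome biogenesis, 7 streak and 4 formative genes fell.

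Targets of p53, which responds to DNA damage and missegregation, did not move as a group in the treated lineages: 17 of 32 were higher (median 0.04, camera adjusted p = 0.995). Of 12 targets named in advance, Phlda3 fell by 0.68 (adjusted p = 0.0433, edgeR). The others did not pass: Cdkn1a, which arrests the cell cycle, stood at 0.31, Mdm2 at 0.23, Gdf15 at 1.97, Bax at -0.60, Eda2r at 0.75, Trp53inp1 at 0.43, Sesn2 at 0.15, Bbc3 at 0.066, Zmat3 at -0.075, Ccng1 at -0.021 and Aen at -0.0059.

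In limma camera, 8 of 31 lists passed in the shared response: trophoblast differentiation and ribosome biogenesis as given above, cholesterol synthesis (adjusted p = 0.000305, or 0.626 with an estimated correlation), the unfolded protein response (0.00205 and 0.389), glycolysis and hypoxia (0.00694 and 0.631), imprinted genes (0.00919 and 0.389), the primitive streak (0.0133 and 0.626) and formative pluripotency (0.0155 and 0.482). With an estimated correlation, 0 lists passed in this or any other fit. The chromosome tests are given with the endoderm lines.

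**Figure D3:**
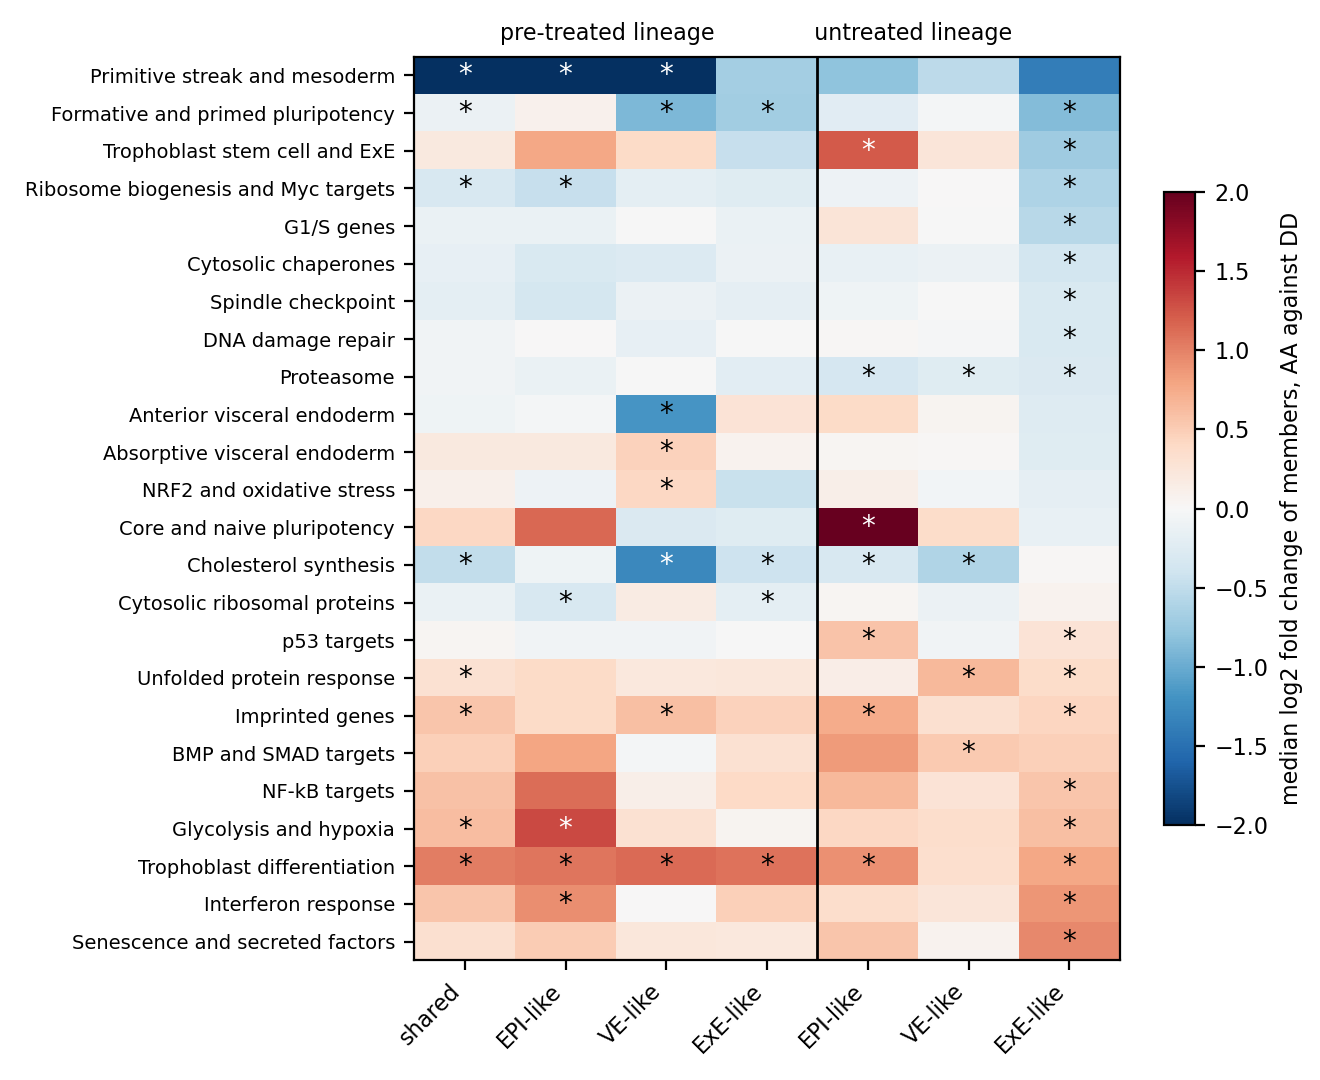
Median log2 change of the members of 24 gene lists between AA and DD in each comparison, with colours capped at 2 and asterisks for camera adjusted p under 0.05 at an inter-gene correlation of 0.01. Cholesterol synthesis was lower in VE-like cells (-1.28), and naive pluripotency was higher in untreated EPI-like cells (2.16).

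In the mixed DA libraries, ribosomal protein genes were slightly lower in the treated lineages, in 40 of 42 members (median -0.23, camera adjusted p = 1.83e-14, or 0.635 with an estimated correlation). Respiratory chain genes were lower in 23 of 27 (median -0.10, adjusted p = 8.97e-05, or 0.635) and absorptive VE genes in 17 of 19 (median -0.42, adjusted p = 0.000497, or 0.635). Trophoblast differentiation genes were higher in 11 of 12 (median 0.22, adjusted p = 0.0169, or 0.635). No member of these lists passed alone. No gene passed in edgeR (0 of 13358, with 162 at an unadjusted p under 0.05), whereas 21 genes, all lower, passed without the AA libraries. Ribosomal protein genes were also lower in DA in untreated EPI-like (41 of 42, median -0.18), VE-like (40 of 42, median -0.29) and ExE-like cells (33 of 42, median -0.14). BC004004 (-0.0049) and Bc1 (0.16) did not differ detectably between DA and DD.

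In EPI-like cells made from treated ESCs, Trh, the precursor of thyrotropin-releasing hormone, fell by 3.37 (SE 0.23, adjusted p = 0.0245, edgeR), from 328 CPM in DD and 344 CPM in DA to 36.0 CPM in AA. It was the only gene to pass, among 2193 at an unadjusted p under 0.05, and DESeq2 called 191. Trh did not pass with the strict cell filter, thinned cells or a linear effect of the reversine share, nor without iGata4 DD, iGata4 DA, TSC DD, TSC DA or TSC AA, which left 0 genes. Without iGata4 AA, 878 genes passed. The spread in this fit holds the AA against DD changes of the other series, so few calls do not show a small response. The next falls did not pass: Cmas (-2.07) of sialic acid synthesis, Arl2bp (-1.66), Fam171b (-2.03) and the cold-shock gene Rbm3 (-1.22). Among the rises that did not pass were the histocompatibility gene H2-D1 (2.36), Ascl2 (2.11), Usp26 (4.94), Tcf15 (2.22) and P4ha2 (2.05). Primitive streak genes were lower in 7 of 8 (median -4.67, camera adjusted p = 0.00171, or 0.698 with an estimated correlation), with T at -6.07, Mesp1 at -5.73 and Mixl1 at -5.09. Glycolysis and hypoxia genes were higher in 20 of 23 (median 1.32, adjusted p = 0.0032, or 0.853), with Aldoc at 2.18 and Slc2a1 at 1.32. Interferon genes were higher in 18 of 19 (median 0.92, adjusted p = 0.0192, or 0.698), with Stat2 at 2.13, and trophoblast differentiation genes in 11 of 12 (median 1.07, adjusted p = 0.0338, or 0.853). Ribosome biogenesis was lower in 19 of 23 (median -0.46, adjusted p = 0.00394, or 0.662), with Srm at -1.05 and Polr1a at -0.80, and ribosomal proteins in 31 of 42 (median -0.32, adjusted p = 0.0192, or 0.853). No member passed over all genes; adjusted over the list alone, 5 streak genes fell and 3 trophoblast, 1 glycolysis and 1 interferon gene rose. Cdkn1a stood at -0.43. These cells lay in cluster 13 in DD and cluster 15 in AA. In 2 of the 3 treated lineages, transcripts carried by some starting lines only differed between AA and DD, so responses of treated lineages can include a change of line.

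In EPI-like cells of the mixed library, 0 genes passed in edgeR (158 at an unadjusted p under 0.05). Ribosomal protein genes were lower in 31 of 42 (median -0.28, camera adjusted p = 0.000807, or 0.998 with an estimated correlation) and parietal endoderm genes higher in 9 of 10 (median 0.42, adjusted p = 0.0105, or 0.998). Background RNA can add to the parietal endoderm genes, as parietal-endoderm-like cells went from 10.4% in ESC DD to 14.1% in ESC DA.

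In VE-like cells made from treated iGata4 ESCs, all 18 cholesterol synthesis genes were lower in AA (median -1.28, camera adjusted p = 7.28e-06, or 0.78 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, stood at -1.49 and Fdps at -1.44, and 13 of the 18 fell when adjusted over the list alone. Anterior VE genes, which pattern the epiblast, were lower in 10 of 13 (median -1.19, adjusted p = 0.01, or 0.72), with Sfrp1 at -1.47, Otx2 at -2.98 and Lhx1 at -1.57. Formative pluripotency genes were lower in 12 of 15 (median -0.90, adjusted p = 0.00945, or 0.567) and streak genes in 5 of 6 (median -2.43, adjusted p = 0.0371, or 0.567). A loss of background RNA can lower these epiblast genes, as EPI-like cells went from 25.6% to 6.94%. Absorptive VE genes were higher in 14 of 21 (median 0.46, adjusted p = 0.00945, or 0.72), with the lipoproteins Apoa1 at 1.63 and Apoa2 at 2.05 and transferrin, Trf, at 1.39. Trf stood at -0.13 when parietal-endoderm-like cells were counted with VE-like cells. Oxidative stress genes were higher in 13 of 17 (median 0.42, adjusted p = 0.00104, or 0.384), with Gclm at 1.17 and Sod1 at 1.15, imprinted genes in 16 of 22 (median 0.60, adjusted p = 0.0371, or 0.72), with H19 at 1.70, and trophoblast differentiation genes in 9 of 11 (median 1.13, adjusted p = 0.0423, or 0.567; 0.0666 with doublets kept). Adjusted over the list alone, 5 anterior VE, 4 formative and 2 streak genes fell, and 6 oxidative stress, 6 imprinted, 4 absorptive VE and 1 trophoblast gene rose. Background RNA of ExE-like cells, whose share went from 45.6% to 89.9% between these libraries, can add to the trophoblast genes.

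No single gene passed in VE-like cells: edgeR called 0, with 1525 at an unadjusted p under 0.05, and DESeq2 called 42. Without ESC AA, edgeR called 327. Other large changes that did not pass were rises of Fgd4 (1.43), Pdgfra (1.03), Nrip1 (1.53) and Slc30a1 (1.06) and falls of Irs4 (-2.61), Gpc4 (-1.29), Aldh1l1 (-2.22) and Npepl1 (-1.84). Cdkn1a stood at 0.61 and Mdm2 at 0.79. The AA library held 304 VE-like cells, against 2386 in DD, and they lay in cluster 5 in AA but in clusters 10 (57.1%) and 4 (40.1%) in DD.

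In VE-like cells of the mixed library, absorptive VE genes went the other way: 16 of 21 were lower than in DD (median -0.48, camera adjusted p = 0.000294, or 0.807 with an estimated correlation). Trf stood at -1.32, Apoa2 at -1.17 and Apoa1 at -0.81, none of which passed. The cells lay in cluster 10 for 57.1% in DD and 93.2% in DA, and within cluster 10 Trf stood at -0.45, Apoa2 at -0.051 and Apoa1 at -0.38, so much of this fall goes with the change of clusters. BMP targets were higher in 11 of 11 (median 0.17, adjusted p = 0.0432, or 0.964). EdgeR called 0 genes, with 213 at an unadjusted p under 0.05, but 79 (5 higher, 74 lower) without the AA libraries.

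Chromosomes 6, 8 and 11 separated the VE-like cells of the iGata4 series. In DA against DD, genes of chromosomes 6 and 8 were higher (medians 0.19 and 0.19, camera adjusted p = 3.11e-07 for both, or 0.022 and 0.00386 with an estimated correlation) and those of chromosome 11 lower (-0.15, adjusted p = 8.67e-07, or 0.00426). In AA against DD the directions were opposite: chromosome 6 was lower (-0.35, adjusted p = 3.18e-05, or 0.0415), chromosome 8 lower (-0.34, adjusted p = 3.18e-05, or 0.00758) and chromosome 11 higher (0.12, adjusted p = 0.0271, or 0.0415). With the other series subtracted, the estimated correlation left none of the 3 passing, in DA (adjusted p = 0.0572 to 0.36) or in AA (0.0871 to 0.219). The same 3 chromosomes passed in EPI-like cells of the ESC series (6, -0.20, adjusted p = 0.00797; 8, -0.16, adjusted p = 0.0344; 11, 0.44, adjusted p = 5.38e-08, with 0.557 to 0.71 with an estimated correlation) and in the shared response to AA (-0.11, -0.13 and 0.19, adjusted p = 0.0252, 0.0183 and 0.00266, or 0.675). In the shared response to DA, chromosome 6 (0.07, adjusted p = 0.0288, or 0.984) and chromosome 11 (-0.05, adjusted p = 0.0288, or 0.984) passed. No chromosome passed in ExE-like cells.

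The pattern was already present among DMSO-treated cells. Within iGata4 DD, VE-like cells of cluster 10 had higher expression than those of cluster 4 across chromosome 6 (median 0.50, with 95.2% of 270 genes above 0) and chromosome 8 (0.48, with 95.1% of 344 genes), and lower expression on chromosome 11 (-0.39), except in the first of 4 segments (-0.066). A score of the 3 chromosomes per cell split the VE-like cells into a low and a high group. The threshold was the midpoint of the cluster 10 and cluster 4 medians in iGata4 DD, so the share in DD follows largely from it. The high group was 59.9% of scored cells in iGata4 DD (95% interval 57.9% to 61.9%), 2007 of 2112 cells in DA (94.0% to 95.9%) and 11.2% in AA (7.90% to 15.3%), and 1.76% to 6.40% in the other series, with at most 4.29% of iGata4 cells near the threshold. Parietal-endoderm-like cells are not counted here, and 31.1% of them were high in iGata4 DD, 46.7% in DA and 53.4% in AA. They made up 95.3% of the high-score endoderm in AA, against 8.79% in DD. The fall among VE-like cells in AA therefore depends in part on how cells were named. When 2 groups were sought among the VE-like cells of each iGata4 library on its own, their means were -0.70 and 0.12 in DD, -0.60 and 0.17 in DA and -0.75 and -0.11 in AA. The upper group in AA was 16.5% of 303 cells and broader, with a standard deviation of 0.25 against 0.13 in DD. DA and DD differed by medians of 0.020, 0.017 and -0.016 on chromosomes 6, 8 and 11 within cluster 10 and 0.055, 0.080 and -0.057 within cluster 4, clusters that these chromosomes help to set apart. EPI-like cells were split at a threshold of their own, the midpoint of 2 group means in EPI-like cells of iGata4 DD. It was -0.585 against -0.284 for VE-like cells, so the groups are not the same. The share of EPI-like cells in iGata4 DD follows largely from this threshold. Above it were 91.4% of EPI-like cells in ESC DD, 94.1% in ESC DA and 18.5% in ESC AA, 55.0% in iGata4 DD and 92.6% in AA, and 58.1% in TSC DD and 55.4% in AA, with 11.1% of cells near the threshold in ESC AA and 11.6% in TSC DD. The score was built after the chromosome tests were seen.

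**Figure D4:**
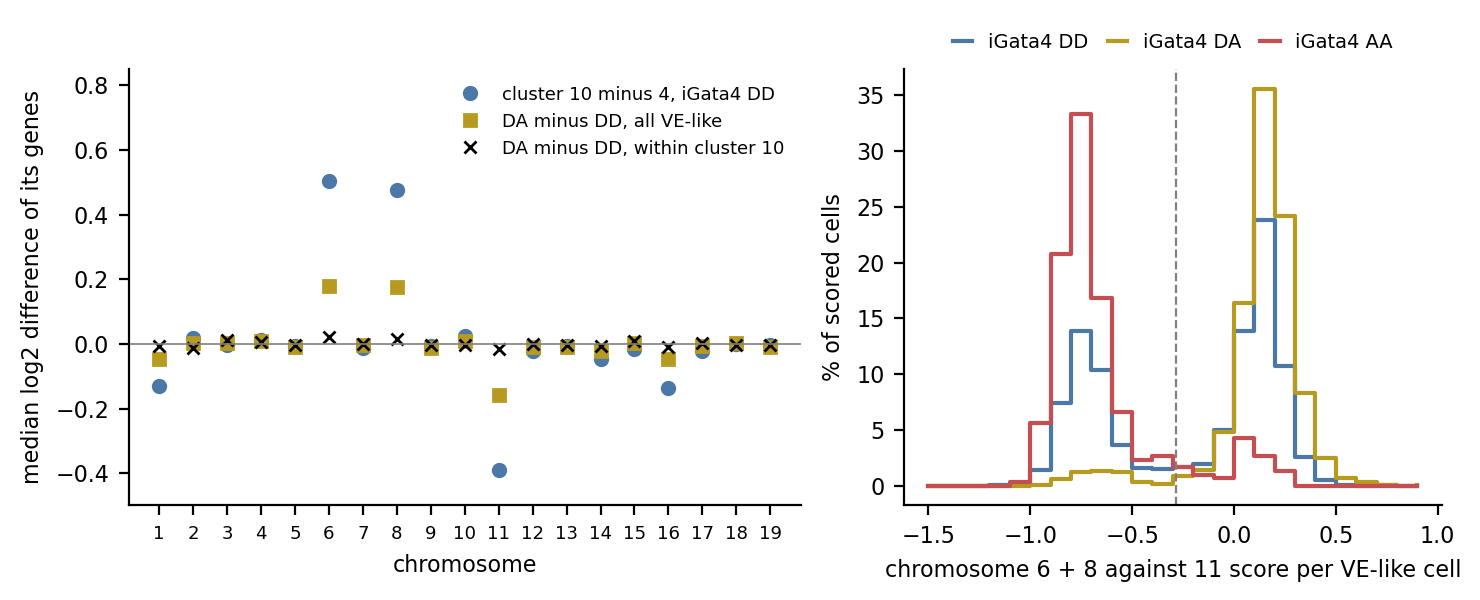
Left, median log2 difference per chromosome for cluster 10 minus cluster 4 in iGata4 DD, for DA minus DD in all VE-like cells and for DA minus DD within cluster 10. Right, percent of VE-like cells by chromosome score in iGata4 DD, DA and AA with the threshold dashed. Above it lie 59.9% in DD and 11.2% in AA, with parietal-endoderm-like cells not counted.

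In ExE-like cells made from treated TSCs, genes of trophoblast differentiation were higher in 15 of 16 (median 1.09, camera adjusted p = 0.00162, or 0.876 with an estimated correlation). Among them were the growth-restraining imprinted genes Cdkn1c (1.38) and Phlda2 (0.92) and the regulator Dlx3 (1.30), and none passed alone. All 18 cholesterol synthesis genes were lower (median -0.41, adjusted p = 0.00126, or 0.876), with Idi1 at -0.45 and Mvk at -0.54. Ribosomal protein genes were lower in 33 of 42 (median -0.20, adjusted p = 0.00791, or 0.876), with Rpl7 at -0.63, and formative pluripotency genes in 13 of 16 (median -0.69, adjusted p = 0.0321, or 0.876), which less background RNA from EPI-like cells can lower (58.8% of cells in DD and 33.4% in AA). No single gene passed in edgeR (0, with 538 at an unadjusted p under 0.05), and DESeq2 called 2. Among the changes that did not pass were rises of P2rx4 (0.98), Lgalsl (0.87), Ugp2 (0.88), Cd59a (1.28) and Clk4 (0.78), and falls of Stat6 (-1.21), the epithelial checkpoint gene Sfn (-2.27), Mrpl23 (-1.31), Cyba (-0.97) and Slc24a5 (-1.11). Cdkn1a stood at 0.64. In the mixed library, ribosomal proteins (40 of 42, median -0.36, adjusted p = 6.69e-06, or 0.991), respiratory chain genes (26 of 27, median -0.27, adjusted p = 0.0005, or 0.756) and absorptive VE genes (14 of 18, median -0.63, adjusted p = 0.00119, or 0.991) were lower, and edgeR called 0 genes (293 at an unadjusted p under 0.05).

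The lineages were compared directly by testing whether the effect of the reversine share differed between them. EdgeR called 0 genes, with 641 at an unadjusted p under 0.05. Leaving out ESC DD gave 32, iGata4 DD 5 and ESC DA 3. Differences between the lineage responses above, such as cholesterol synthesis in VE-like cells, are therefore not shown to be specific to a lineage.

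Untreated EPI-like cells, in structures whose VE or ExE precursors had been treated, had higher levels of naive pluripotency genes in AA. Of 17 core and naive pluripotency genes, 16 were higher in AA (median 2.16) and 11 passed, among them Klf5, Esrrb (3.76), Dppa3 (2.63) and Dppa5a (2.50). Dppa3, a germline and naive-state gene, went from 17.0 to 145 CPM in the iGata4 series and from 14.6 to 69.8 CPM in the TSC series. Of 33 p53 targets, 30 were higher (median 0.57) and 12 passed, among them Btg2 (1.48, adjusted p = 0.00263, edgeR), Plk2 (1.76), Gdf15 (2.81), Cdkn1a (1.36) and Mdm2 (1.10). Trophoblast stem cell genes were higher in 15 of 17 (median 1.23), 8 of which passed, among them Rhox6 (2.94); background RNA of ExE-like cells, whose share rose in both series (45.6% to 89.9% and 14.1% to 31.2%), can add to these. Trophoblast differentiation genes were higher in 10 of 12 (median 0.92), 5 of which passed. Of 22 imprinted genes, 10 rose, including Peg10 (3.13), Igf2 (2.34) and H19 (1.57), and 2 fell, including Grb10 (-1.46). Proteasome genes were lower in 26 of 27 (median -0.33, 0 passed) and cholesterol synthesis genes in 13 of 18 (median -0.33), with falls of Hmgcs1 (-0.67) and Cyp51 (-0.70). Adjusted over the list alone, 12 pluripotency, 18 p53, 11 trophoblast stem cell, 7 trophoblast differentiation and 13 imprinted genes rose, and 3 cholesterol genes fell.

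By the naming rule, the largest rises in untreated EPI-like cells were in Smtnl1, Hspa1b, Fbxo15, Rpl39l, BC004004, AU018091, Ipp and Triml2, from 3.67 to 5.85. The largest falls were in Bc1, Xaf1, Pbld1, Slamf1, Nutf2-ps1, Rnaset2a, Olfr889, Dennd5b, Hist1h2ab and Wdcp, with a smallest size of -3.12. In all, 1358 of 13863 genes passed, 837 higher and 521 lower. In simulated data, 28 of 136 calls in this fit were of unchanged genes. The count was 582 without iGata4 DD, 2723 without iGata4 AA and 5401 without TSC AA. Of the genes named for these cells, Smtnl1, Hspa1b, Ipp, Bc1, Mdm2, Rhox6, Hmgcs1 and Cyp51 lost their call without 1 or 2 of the iGata4 or TSC libraries. The 7 lists above had camera adjusted p of 1.91e-06 (p53 and pluripotency), 6.07e-05 (trophoblast stem cell), 0.0044 (proteasome and imprinted), 0.00548 (trophoblast differentiation) and 0.0393 (cholesterol), and 0.725 to 0.872 with an estimated correlation. Chromosome 8 was higher (median 0.34, camera adjusted p = 2.18e-07, or 0.814). These calls are not shown to be a response to treated neighbours: transcripts carried by some starting lines only differed between AA and DD (over 2-fold, with intervals apart and at least 10 CPM in the higher) in 4 of 9 pairs of lineage and series, and in 0 of 9 between DA and DD, so a change of line can give such differences as well.

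Untreated VE-like cells had higher levels of unfolded protein response genes in AA. All 22 measured members were higher (median 0.65, camera adjusted p = 4.92e-10, or 0.856 with an estimated correlation) and 9 passed, among them Herpud1 (1.40, adjusted p = 0.00238, edgeR) of endoplasmic reticulum quality control, Ppp1r15a (1.32) and Dnajb9 (1.35). BMP targets were higher in 10 of 11 (median 0.52, adjusted p = 0.00413, or 0.856), of which Id2 (1.06) passed. Cholesterol synthesis genes were lower in 18 of 18 (median -0.59, adjusted p = 3.76e-06, or 0.856), of which the regulator Srebf2 (-0.78) passed, and proteasome genes in 23 of 27 (median -0.23, adjusted p = 0.00413, or 0.856), of which 0 passed. Adjusted over the list alone, 18 unfolded protein response and 5 BMP genes rose and 12 cholesterol genes fell. Hspa1a rose by 6.92 (adjusted p = 9.43e-06) and Gdf15 by 2.83. Other large rises were in Hspa1b (4.61), Rpl29 (2.36), Zfp36, BC004004, Maff, Rora, Stk17b and Ddit3. The largest falls were in Bc1, Xaf1, Nutf2-ps1, Rnaset2a, Rpl9-ps6, Hist1h3c, Rps27rt, Rpl10-ps3, Fosb and Hypk. In all, 350 of 12627 genes passed, 190 higher and 160 lower. They are not shown to be a response to treated neighbours either, because differences of the AA libraries as wholes are confounded with it. The count was 97 without ESC DD, 109 without TSC DD, 1083 without ESC AA, 1233 without ESC DA, 1234 without TSC DA and 4027 without TSC AA. Without ESC DD, Zfp36, Maff, Ddit3, Fosb, Dnajb9, Srebf2, Id2 and Gdf15 did not pass.

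Untreated ExE-like cells of AA structures had lower levels of G1/S and trophoblast stem cell genes and higher levels of trophoblast differentiation genes. Of all 14497 genes tested in these cells, 2713 rose and 2635 fell, against which the counts of members below must be read. Of 26 G1/S genes, 25 were lower (median -0.56) and 19 fell, among them Ccne1 (-1.08, adjusted p = 0.000839, edgeR), Mcm5 (-0.82) and Ung (-0.92). Of 18 trophoblast stem cell genes, 14 fell (median -0.72), including the stem cell regulators Eomes (-1.37), Esrrb (-1.77) and Elf5 (-1.01), and 2 rose. Of 13 trophoblast differentiation genes, 8 rose (median 0.77), including Peg10 (1.83), Plac1 (2.06), Gata2 (1.83) and Krt8 (1.98). Of 23 ribosome biogenesis genes, 17 fell (median -0.62), including Rrp9 (-1.43) and Polr1b (-1.48), and 2 rose. Of 32 p53 targets, 13 rose, including Cdkn1a (1.63, adjusted p = 0.00222), Btg2 (1.84) and Plk2 (1.41), and 3 fell, including Bax (-0.60). Of 14 NF-kB targets, 6 rose, including Ccl2 (3.12) and Nfkbia (1.18). Of 12 senescence genes, 8 rose and 1 fell. Of 23 glycolysis and hypoxia genes, 15 rose, including Egln3 (1.69) and the glucose transporter Slc2a3, and 1 fell. Of 21 interferon genes, 12 rose, including Usp18 (2.42) and Ifi27 (1.58), and 2 fell. The other 7 lists that passed were imprinted genes (13 rose, 4 fell), the unfolded protein response (10 rose, 3 fell), DNA repair (12 fell), the spindle checkpoint (8 fell, 1 rose), chaperones (12 fell, 2 rose, with a median of -0.36 but a mean of 0.03), the proteasome (11 fell) and formative pluripotency (9 fell, 2 rose). Adjusted over the list alone, 22 G1/S, 14 trophoblast stem cell and 18 ribosome biogenesis genes fell, and 16 p53, 9 trophoblast differentiation and 15 glycolysis genes rose.

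By the naming rule, the largest rises in untreated ExE-like cells were in Creb5, Dkk1, Hspa1b, Tanc2, Krt19, Myl4, Atf3, BC004004, Rpl29 and Lgals3, from 2.59 to 5.38. The largest falls were in Bc1, Nutf2-ps1, Aldh1a3, Rnaset2a, Dennd5b, Mpv17l, Tmem238, Rpl9-ps6, Rhox4g and Hist1h3c. In all, 5348 of 14497 genes passed, 2713 higher and 2635 lower, and 2000 without ESC DD or 2188 without iGata4 DD. The cells lay mostly in clusters 0 and 1 in DD and in clusters 2 and 9 in AA. These calls are not shown to be a response to treated neighbours, because differences of the AA libraries as wholes are confounded with it. Hspa1b, Aldh1a3, Dennd5b and Bax lost their call without at least 1 of the ESC or iGata4 DD or DA libraries. Cluster 18, left unnamed for few UMIs, had a median of 16.2% mitochondrial UMIs. It held 550 cells in ESC AA and 367 in iGata4 AA, against 32 to 44 in the DD and DA libraries of these series. Whether cell quality bears on the stress and p53 genes was not tested. The 16 lists had camera adjusted p from 4.09e-06 (G1/S) to 0.0356, and from 0.41 to 0.605 with an estimated correlation. In DA against DD, edgeR called 0 genes in untreated EPI-like (101 at an unadjusted p under 0.05), VE-like (294) and ExE-like cells (239).

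The spread of chromosome shares between cells was compared because cells with unequal chromosome gains would differ in the share of transcripts from each chromosome. The excess coefficient of variation was 6.59% in ESC DD, 6.14% in DA and 8.36% in AA for EPI-like cells. For VE-like cells of the iGata4 series it was 7.53%, 6.38% and 9.03%, and for ExE-like cells of the TSC series 7.24%, 8.32% and 7.55%. Without chromosomes 6, 8 and 11 the iGata4 values were 5.99%, 5.97% and 8.52%, so the fall from DD to DA lay in these chromosomes. The cells deep enough to be used were 330 of 1185 in TSC DD but 2509 of 2826 in TSC AA. In the ESC series they were 396 of 1239 in DA but 639 of 792 in AA. AA minus DD averaged 1.19 points and did not pass (exact permutation p = 0.222, smallest possible 0.009). Without the 200 highest genes it averaged 0.468, with the TSC series at -0.144. In the untreated lineages of the same libraries the average was 1.25 (exact permutation p = 0.0463).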

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

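The tests of explanations in this part were chosen after the results were seen.

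The share of the treated lineage moved in opposite directions between the series, and the difference between them was not tested. The AA minus DD log-odds were -0.343 for EPI-like cells of the ESC series, -2.50 for VE-like cells of the iGata4 series and 1.02 for ExE-like cells of the TSC series. A naming of VE-like cells as parietal endoderm does not account for the whole fall in the iGata4 series: counted together, VE-like and parietal-endoderm-like cells still stood at -1.01. Loss of treated cells and differences in assembly, dissociation or capture cannot be told apart, with 1 library per group. ExE-like cells, which were untreated in the iGata4 series, differed there by 2.36, and the treated ExE-like cells of the TSC series had the positive value of 1.02. The 2.36 is not independent of the fall of VE-like cells, because the shares of a library are parts of 1 whole.

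Parietal-endoderm-like cells, which the comparisons leave out, were 12.1% of the cells of iGata4 AA against 5.18% in DD and 1.80% in DA, without a test between libraries. They were 10.4%, 14.1% and 11.5% in ESC DD, DA and AA, and 16.2%, 14.7% and 11.2% in the TSC series. Clusters 11 and 19, whose cells had few UMIs and few mitochondrial UMIs and were left unnamed, held 6.02%, 3.29% and 12.3% of the clustered cells of ESC DD, DA and AA, 0.773%, 2.20% and 19.02% in the TSC series, and 5.23%, 6.06% and 5.45% in the iGata4 series. No explanation of these shares was tested.

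The genes called between AA and DD in the treated lineages were weighed as a pattern. An effect confined to treated cells is argued against, since 99.0% of them had the same sign in the untreated lineages. Deeper sequencing of AA cells is argued against among cells with at least 5000 UMIs, since 296 genes were called with these thinned to 5000. Cells with fewer UMIs were left out, and 379 of 1185 ExE-like cells of TSC DD but 2581 of 2826 of TSC AA were kept. A difference in which cells were kept is therefore not excluded. A difference of the AA libraries as wholes, in preparation, sequencing, alignment or starting line, may contribute: Bc1, BC004004 and 4 other genes, 6 in all, differed beyond 2-fold in every class of the AA libraries, and no gene did so for DD or DA. Transcripts carried by some starting lines only differed over 2-fold, with intervals apart and at least 10 CPM in the higher, between AA and DD in 4 of 9 pairs of lineage and series (2 of 3 treated, 2 of 6 untreated), and between DA and DD in 0 of 9, which a change of line in AA would give. Effects of treated cells on their neighbours stay open too, as they are confounded with such differences here.

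By the share of splits alone, chance cannot be excluded for this count. Of 60 splits of the labels within lineages, 4 called as many genes as the real 313, the real one included, and the highest other gave 542. The other 3 (504, 347 and 542) kept each AA label and exchanged only DD with DA, so they hold the same AA libraries, and each split that moved an AA label called 0. For DA against DD the real count was 0, so all 47 distinct splits had to call as many, and this says nothing about chance. The highest other, 347, came from a split that named each AA library DA, and points to the same structure, in which AA stands apart.

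The changes of chromosomes 6, 8 and 11 in VE-like cells of the iGata4 series were weighed last. Gains or losses made by the reversine treatment are argued against as their origin, since VE-like cells of iGata4 DD, which had DMSO, already differed in this way. There, cluster 10 exceeded cluster 4 by a median of 0.50 on chromosome 6 and 0.48 on chromosome 8. The 59.9% of these cells in the high group is no separate support, because the threshold was set between the 2 clusters in iGata4 DD. A few regulated genes are argued against for chromosomes 6 and 8, since each of 4 segments of chromosomes 6 and 8 was higher in cluster 10 than in cluster 4, the lowest median being 0.44. On chromosome 11 a shift along the whole chromosome is argued against, since the first segment stood at -0.066 against -0.39 for all of it. A candidate explanation is that cell lines with different chromosome content were present in changing proportion. The 2 groups sought in each library on its own had means shifted by at most 0.23 from those of DD, which lie 0.82 apart. This is limited support, because the number of groups was set at 2 in each library. In AA the upper group was 16.5% of 303 cells, with a standard deviation of 0.25 against 0.13 in DD. The groups also leave out parietal-endoderm-like cells, which were 95.3% of the high-score endoderm in AA. The text of the design mentions differently labelled cells, but which line carries which label is not given in the sources used.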

How the results depend on the processing

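The settings that leave out the AA libraries, subtract the other series or the other lineages, count parietal-endoderm-like cells as VE-like, exchange or drop chromosomes in the dispersion, or estimate the correlation outside the planned list tests were chosen after seeing the data, as was leaving out libraries for the shared DA, untreated and lineage-difference results. Where a value moved, the cause was not tested. Using only the largest cluster of each class was not run, because under 50 cells were left in libraries it needs.

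For AA against DD in the treated lineages, 313 genes passed. Without a filter on low counts 1479 passed (863 higher, 616 lower), with DESeq2's Wald test 733, with a linear effect of the reversine share 6, and with the other lineages subtracted 0. Leaving out single libraries gave 43 to 1623: TSC DD 43, iGata4 DD 51, ESC DD 67, iGata4 DA 153, ESC DA 189, iGata4 AA 201 and TSC AA 1623. The other 5 settings lay within 1.5 times. For DA against DD, 0 became 10 without the filter and 21 without the AA libraries, and stayed 0 (0 to 0) with single libraries left out.

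For EPI-like cells in AA, 1 gene became 191 with DESeq2's Wald test, 72 with the other series subtracted and 0 with the linear effect, the strict filter or thinned cells. Leaving out libraries gave 0 to 878 (878 without iGata4 AA, 0 without iGata4 DD, iGata4 DA, TSC DD, TSC DA or TSC AA). For VE-like cells in AA, 0 became 4 without the filter and 42 with DESeq2, and 0 to 327 with libraries left out (327 without ESC AA). For ExE-like cells in AA, 0 became 2 with DESeq2 and stayed 0 (0 to 0) with libraries left out. For VE-like cells in DA, 0 became 3 without the filter, 5 with the other series subtracted and 79 without the AA libraries. EPI-like and ExE-like cells in DA kept 0 in 5 settings each.

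For untreated EPI-like cells 1358 became 2895 without the filter and 582 to 5401 with libraries left out (582 without iGata4 DD, 2723 without iGata4 AA, 5401 without TSC AA). For untreated VE-like cells 350 became 1172 without the filter and 97 to 4027 with libraries left out (97 without ESC DD, 109 without TSC DD, 1083 without ESC AA, 1233 without ESC DA, 1234 without TSC DA, 4027 without TSC AA). For untreated ExE-like cells 5348 became 2000 to 7520 (2000 without ESC DD, 2188 without iGata4 DD). For DA, 0 became 26 in untreated VE-like cells without the filter. The lineage difference went from 0 to 148 without the filter and to 0 to 32 with libraries left out (32 without ESC DD, 5 without iGata4 DD, 3 without ESC DA).

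With an estimated correlation, 0 gene lists passed in each of the 14 comparisons in which lists had passed at 0.01. With the other series subtracted, the lists that passed went from 6 to 11 in EPI-like AA, from 4 to 7 in ExE-like AA and from 2 to 1 in EPI-like DA, and with the other lineages subtracted from 4 to 0 in the shared DA response. Of the chromosomes, 0 passed with an estimated correlation in the shared AA and DA responses and in treated and untreated EPI-like cells in AA, whereas all 3 passed in VE-like cells in AA and in DA. With the other series subtracted as well, 0 passed there.

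The share of the treated lineage kept its sign and did not pass in 5 settings, from -0.809 to -0.103. The strict filter moved the TSC difference from 1.02 to 0.324 and the ESC difference from -0.343 to -0.134. With a series left out the average ranged from -1.42 to 0.338, reversing at 0.338 without the iGata4 series. The dispersion of chromosome shares stayed positive and did not pass in 4 settings, at 0.468 without the 200 highest genes and 1.78 without chromosomes 6, 8 and 11, and ranged from 0.903 to 1.64 with a series left out. Without the 200 highest genes, only 8 cells were left in ESC DA and 63 in ESC DD. In the untreated lineages it passed at 1.25, and treated minus untreated lineages reversed it to -0.0588.

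For 210 results of named genes, 2716 values were computed under other settings: 2367 kept direction and side of the threshold, 227 no longer passed, 82 passed newly and 40 reversed. With the other lineages of the library subtracted, the shared response reversed for Hspa1a (-0.98), Hspa1b (-0.066), Rpl39l (-0.32), BC004004 (-0.25), Rnaset2a (0.21), Rpl9-ps6 (0.078), Dennd5b (0.74), Hypk (0.0076), Cdkn1a (-0.71), Mdm2 (-0.53), Trp53inp1 (-0.35), Bbc3 (-0.27), Eda2r (-0.38), Aen (0.15), Sesn2 (-0.63), Gdf15 (-0.90), Ppp1r15a (-0.23), Dnajb9 (-0.16), Atf3 (-0.23), Peg10 (-0.42), Gata2 (-0.38) and Hand1 (-0.014). None of these passed there. Aen, at -0.0059, was positive with DESeq2 size factors (0.00082), DESeq2's Wald test (0.0013), the strict filter (0.015), thinned cells (0.092) and parietal-endoderm-like cells counted (0.057). Ccng1, at -0.021, was positive with thinned cells (0.015) and parietal-endoderm-like cells counted (0.016). With single libraries left out, Aen ranged from -0.17 to 0.17, Ccng1 from -0.14 to 0.065 and Mdm2 from -0.049 to 0.47. Trf reversed to -0.13 with parietal-endoderm-like cells counted, and Cdkn1a in ExE-like cells to -0.99 with the other series subtracted. Of 18 percentages of cells in the high group, 14 stayed within the interval of the main value, and 4 moved.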

Other observations

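The tests in this part were chosen after the results were seen.

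Without the AA libraries, 74 genes were lower in VE-like cells of iGata4 DA than of DD, with a median of -1.23. Most were also lower in cluster 10 than in cluster 4 of iGata4 DD (73 of 74, median -1.83). The larger proportion of cluster 10 in DA (93.2% against 57.1%) may account for part of the falls, since a median of -0.80 was expected from the proportions alone. Within cluster 10, 65 of 67 genes with a value were still lower in DA (median -0.45). Whether the proportions account for all of the falls is open, because the genes were chosen as lower in DA in the same libraries.

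Low-score endoderm, counted over VE-like and parietal-endoderm-like cells, was 14.4% of the cells in iGata4 DD, 2.03% in DA and 8.12% in AA. High-score endoderm was 17.9%, 21.7% and 6.75%. In AA, 95.3% of the high-score cells were parietal-endoderm-like, against 8.79% in DD. No explanation was tested for these shares, since each group is 1 library and which line was treated is not given in the sources used.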
